A study of Homo sapiens with 4 samples.

How the data were processed

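Gene expression was measured on 4 arrays in SH-SY5Y cells, an established human neuroblastoma line that takes on neuron-like features when it is differentiated. Per the labels, 2 arrays hold RNA from cells with a control short hairpin RNA (shRNA) and 2 hold RNA from cells with an shRNA against LSD1+8a. LSD1+8a is the splice form of the histone demethylase LSD1 (gene KDM1A) that contains the extra exon 8a. Per the labels' protocols, all cells received 10 μM retinoic acid for 4 days and then 50 ng/mL BDNF, a neurotrophin, without serum for 3 days. Total RNA was isolated with a silica-column kit, 250 ng was copied into biotin-labelled cDNA, and the product was hybridised to the second version of the Affymetrix human transcriptome array.

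The deposited values are log2 signals, 1 value per feature and array, which the authors made with RMA, per the submitters' processing notes. RMA as generally run subtracts a background, normalises between arrays and summarises the probes of a feature. Its software, version and annotation, and the genome build, are not given in the sources used here, so no coordinates are printed. RMA keeps no detection call, so a dim gene cannot be told from an unexpressed one. It also does not remove differences in background between arrays that depend on the base composition of the probes.

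The table holds 70523 features. Of these, 67528 are transcript clusters and 2995 are others, among them 23 background features sorted by GC count and 155 ERCC features, which were left out of the tests. The platform's gene table gave 1 symbol to 23781 transcript clusters and several symbols to 1543, and 42204 were unnamed. Clusters with 1 symbol gave 22465 genes. Where a gene had several clusters (479 genes), the one with the highest mean over the 4 arrays was used. The RefSeq gene table held 22164 of these symbols, and the other 301 kept the name in the platform table. No coordinates, probe sequences or GC contents were used here.

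The comparison was LSD1+8a shRNA minus control shRNA, tested per gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default moderation) on the values as deposited, without a filter and without a replicate term. P-values were adjusted by the Benjamini-Hochberg method over all 22465 genes, with a threshold of 0.05. Errors beside group means are standard deviations over 2 arrays, and errors beside differences are limma's standard errors (SE). Nothing in the labels says whether replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Precision is limited by the number of arrays: 2 residual degrees of freedom per gene, plus 5.41 borrowed from all genes.

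Of 25 gene lists fixed before the data were examined, 24 were tested with limma's camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01. The list of mitochondrially encoded genes had no measured member. P-values were adjusted over the 24 lists. Beside it, camera with a correlation estimated per list and fry, which asks whether a list's genes move on balance 1 way, were run. With an estimated correlation, and with fry, no list passed, so every list call rests on the preset correlation. Fixed members were matched by symbol or by an older symbol in the gene table.

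The rule for named genes, also fixed before the data were examined, takes KDM1A and SVIL, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups did not overlap, and up to 6 called members of each list by size (2 members where none was called). Unnamed loci, microRNA, small nuclear and small nucleolar RNA genes and pseudogenes were skipped among the 24. Of the 149 genes this takes, the text names a part.

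The tests were tried on simulated data with the mean levels of this comparison over 22465 genes, and 50 genes changed at each size. Variances were drawn from limma's fitted prior, and genes were simulated as independent. Changes of 0.4 on the log2 scale were recovered in 6.0% of genes, of 0.6 in 38.0%, of 1 in 92.0% and of 2 in 100.0%, and 6 of 124 calls were false. Camera found a simulated list shifted by a fixed amount and called 0 of 99 unshifted lists. Far fewer genes were changed than were called in the real data, so the recovered shares need not hold there. Independent genes cannot show whether the preset correlation is suitable.

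Other settings, also fixed before the data were examined, were leaving out each array, the replicate number as a block, quantile normalization and median centring of the deposited values, trended and robust moderation, a filter that keeps genes above the median level, the mean over a gene's clusters, all transcript clusters, and other thresholds. Cyclic loess between arrays and a restriction to protein-coding genes were added after seeing the data. Figures were drawn with matplotlib 3.10.9.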

Results

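The series asked which genes depend on LSD1+8a, the neuronal splice form of the histone demethylase LSD1, in differentiated SH-SY5Y neuroblastoma cells. Transcript levels were compared between 2 arrays of cells with an LSD1+8a shRNA and 2 arrays of cells with a control shRNA, after retinoic acid and BDNF. Median log2 signals over the 22465 genes were 6.19 and 6.16 on the control arrays and 6.20 and 6.25 on the LSD1+8a shRNA arrays. Replicate arrays were close, with a standard deviation of the difference between them of 0.177 for the control pair and 0.171 for the LSD1+8a pair, against 0.274 to 0.362 between arrays of different groups.

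KDM1A, the gene that encodes LSD1, was lower with the LSD1+8a shRNA. Its transcript cluster (TC01000292.hg.1) had a log2 signal of 9.18 ± 0.11 (SD, n = 2) in control cells and 8.77 ± 0.015 (SD, n = 2) in LSD1+8a shRNA cells. The difference was -0.41 ± 0.09 (SE), which is 1.32-fold lower, with a limma adjusted p of 0.0299. This value summarises the gene as a whole and cannot isolate exon 8a, so it does not check the level of LSD1+8a itself. The adjusted p rose to 0.0610 after quantile normalization (difference -0.28) and to 0.0586 after cyclic loess (difference -0.29). With 1 array left out it was 0.0666 without control replicate 1, 0.194 without control replicate 2, 0.0856 without LSD1+8a replicate 1 and 0.0559 without LSD1+8a replicate 2. SVIL, which encodes the actin-binding protein supervillin, had a log2 signal of 7.02 ± 0.03 in control and 6.69 ± 0.28 in LSD1+8a shRNA cells (SD, n = 2), a difference that did not pass the test (limma adjusted p = 0.0945).

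Differences between the groups were many and mostly small. With limma, 5245 of 22465 genes passed an adjusted p of 0.05, of which 2721 were higher and 2524 lower with the LSD1+8a shRNA. The median size among them was 0.40 on the log2 scale. Of these genes, 135 were at least 1.5-fold higher and 670 at least 1.5-fold lower, and 20 were at least 2-fold higher against 128 lower. At an unadjusted p under 0.05 there were 10124 genes, where 1123 would be expected by chance, and 858 of them differed by at least 1.5-fold, 143 higher and 715 lower. The groups did not overlap for 74.4% of genes, where chance gives 33.3% for 2 arrays against 2.

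The share of higher calls depended on the scaling. Genes with a mean log2 signal between 5 and 6 had a median difference of 0.21, and genes between 8 and 10 one of -0.09. Centring each array on its median lowered the median difference over all genes from 0.08 to -0.04 and left 3859 genes called, 384 of them higher, which put 10.0% of calls on the higher side instead of 51.9%. After cyclic loess, which removes the dependence on level, 702 genes were higher and 1909 lower (26.9% higher). Of the 1.5-fold calls, 101 of 135 higher and 586 of 670 lower genes were also called after cyclic loess, and none changed sign. Without control replicate 1 or without control replicate 2, limma called 0 genes (9835 and 5339 at an unadjusted p under 0.05), and it called 1355 without LSD1+8a replicate 1 and 2834 without LSD1+8a replicate 2.

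**Figure D1:**
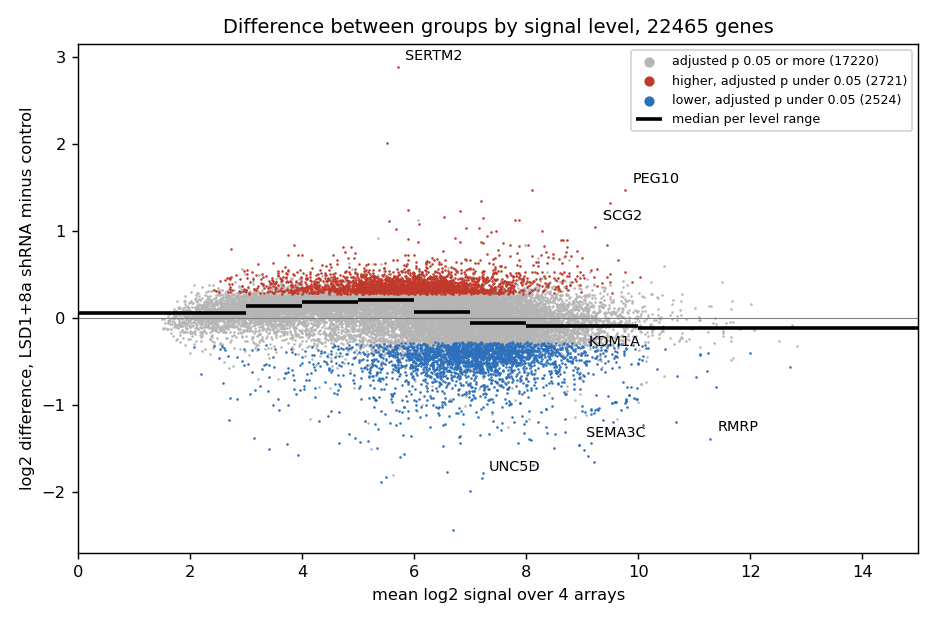
Each point is 1 of 22465 genes, with its mean log2 signal over the 4 arrays on the x axis and the log2 difference between LSD1+8a shRNA and control on the y axis. Red points (2721) were higher and blue points (2524) lower at a limma adjusted p under 0.05, and black bars give the median difference per level range, which goes from 0.21 at 5 to 6 to -0.11 above 10.

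The 12 largest rises ran from 1.13 (SLC18A1) to 2.89 (SERTM2) on the log2 scale. SERTM2 rose from 4.26 ± 0.58 to 7.14 ± 0.49 (log2 signal, SD, n = 2), a difference of 2.89 ± 0.29 (SE; limma adjusted p = 0.00612). EDIL3, a secreted integrin ligand, rose by 2.02 ± 0.40 (SE). In control cells EDIL3 (4.50) lay within the control arrays' medians of background features of GC counts 13 to 18 (4.43 and 4.50). SERTM2 lay below them, so the sizes of both rises are uncertain. Single counts ran from 2.81 at 13 to 6.13 at 18 over the 4 arrays. As the genes' GC contents were not used, these medians are a rough guide. PEG10, an imprinted gene of retrotransposon origin, rose 2.77-fold from 9.03 ± 0.15 to 10.50 ± 0.06 (SD, n = 2; limma adjusted p = 0.00356). PCDH17, a protocadherin, rose 2.55-fold, TFPI2, a secreted protease inhibitor, 2.49-fold, and LRRTM1, a synaptic adhesion protein, 2.22-fold. PRLHR, a neuropeptide receptor, rose 2.24-fold and SLC18A1, a vesicular monoamine transporter, 2.19-fold. The other genes among the 12 largest rises were SLCO4C1 (2.78-fold), MBOAT4 (2.37-fold), IGHA1 (2.36-fold) and DHCR7 (2.32-fold). SLCO4C1 read 9.59 and 8.09 on the LSD1+8a shRNA arrays against a control mean of 7.37, so replicate 1 carries much of its rise. After cyclic loess, EDIL3 (adjusted p = 0.0529) and SLCO4C1 (0.0714) no longer passed, and the other 10 did. The log2 differences of EDIL3 and SLCO4C1 there were 1.86 and 1.55.

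The 12 largest falls included genes of an axon guidance receptor and of a secreted guidance protein. UNC5D, a netrin receptor, fell 3.57-fold from 8.12 ± 0.15 to 6.29 ± 0.44 (SD, n = 2; limma adjusted p = 0.00651). SEMA3C, a secreted semaphorin, fell 2.74-fold from 9.67 ± 0.03 to 8.21 ± 0.10 (SD, n = 2; limma adjusted p = 0.00335). VCAN, the extracellular matrix proteoglycan versican, fell 2.45-fold. Its antisense gene VCAN-AS1 fell from 6.35 to 4.47 in the cluster used. The lower value lies below the background medians of the LSD1+8a shRNA arrays (4.71 and 4.72), so the size of its fall is uncertain. A second cluster of that gene differed by only -0.19, and the antisense value cannot be separated here from overlap with VCAN. CSRP2, a LIM-domain protein, fell 3.23-fold, CNKSR2, a postsynaptic scaffold protein, 2.70-fold, TXNIP, a thioredoxin inhibitor, 2.62-fold, and the zinc finger gene ZNF521 2.54-fold. BRIP1, a DNA repair helicase, fell 2.44-fold and RMRP, the RNA of the RNase MRP complex, 2.61-fold. The interferon-stimulated genes IFI44 and IFI44L, also among these 12, had means of 4.70 and 4.15 in control cells. Background medians of GC counts 13 to 18 were 4.50 and 4.43 there, so IFI44 lay above them and IFI44L below. With the LSD1+8a shRNA their means were 3.14 and 2.64, below the medians of 4.71 and 4.72, so no size is given. IFI44 did not pass after cyclic loess (adjusted p = 0.0505).

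**Figure D2:**
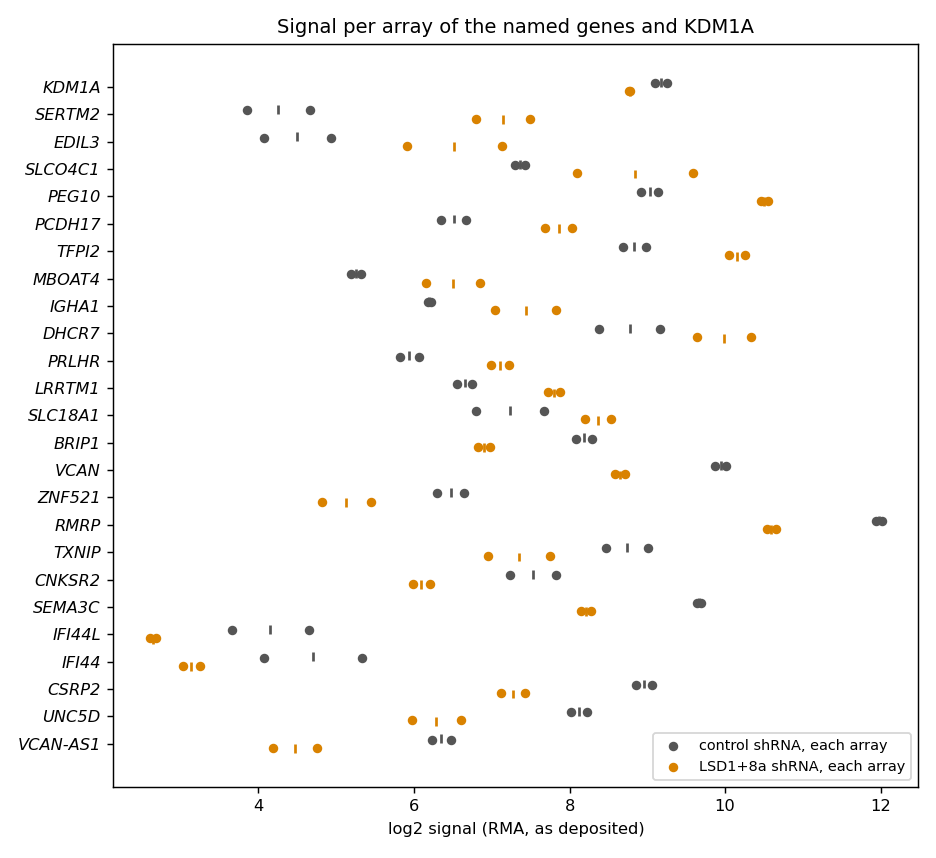
Log2 signal on each array (points) and group means (vertical bars) for the 12 genes with the largest rise, the 12 with the largest fall and KDM1A. The 24 genes were taken from those whose groups did not overlap, and the spread of replicates differed between them, from 0.03 in IGHA1 and SEMA3C to 0.89 in IFI44 among control arrays (SD, n = 2).

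Genes of cell division and DNA replication fell together. Of 37 genes active in G2 and mitosis, 30 fell, 0 rose and 7 did not pass over all genes tested (32 fell adjusted over the list alone), with a median difference of -0.58. CDK1, the mitotic kinase, fell 2.12-fold, the kinesin KIF11 1.97-fold, and the kinetochore genes NDC80 and NUF2 1.93-fold and 1.93-fold. Of 36 replication and S phase genes, 24 fell, 0 rose and 12 did not pass (29 fell adjusted over the list alone), with a median of -0.49. The primase subunit PRIM1 fell from 7.37 ± 0.08 to 6.30 ± 0.08 (SD, n = 2; limma adjusted p = 0.00445), and PCNA, the DNA polymerase clamp, fell 1.99-fold, GINS2 1.90-fold and MCM10 1.76-fold. Of 36 replication-dependent histone genes, 18 fell and 1 rose (23 and 1 adjusted over the list alone), with a median of -0.53, including H4C3 (2.28-fold) and H1-2 (2.12-fold). Limma's camera gave adjusted p-values of 3.87e-18, 7.12e-18 and 2.02e-12 for the 3 lists. None passed with an estimated correlation (adjusted p = 0.490 for each).

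Small nucleolar RNAs, several other classes of short RNA and ribosomal protein genes were lower in the same arrays. MicroRNA genes were not, with 189 of 1040 called higher and 26 lower. Of 258 small nucleolar and Cajal body RNAs, 112 fell, 4 rose and 142 did not pass (125 fell and 7 rose adjusted over the list alone), with a median of -0.51. SNORA20 fell 5.39-fold from 7.90 ± 0.38 to 5.47 ± 0.34 (SD, n = 2), SNORA12 3.97-fold and SNORD58C 3.42-fold. Other short RNAs with levels above the median gene (small nuclear, Y and RNase RNAs) had a median of -0.89 over 72 genes, many of which are near-identical copies that share probes. Of 51 ribosomal protein genes, 30 fell and 0 rose (41 fell adjusted over the list alone), with a median of -0.32, including RPS15A (1.73-fold), RPL9 (1.70-fold) and RPL24 (1.61-fold). Without LSD1+8a replicate 1 the median of the small nucleolar and Cajal body RNAs was -0.28. After cyclic loess 12 of the 51 were called, and RPS15A was not (adjusted p = 0.0882). Ribosomal protein genes have many processed copies whose transcripts could share probes. Limma's camera gave adjusted p-values of 6.03e-21 for small nucleolar and Cajal body RNAs and 6.13e-16 for ribosomal proteins, and neither passed with an estimated correlation (adjusted p = 0.490 for both).

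Lists of neuronal secretory and synaptic genes stood higher than other genes by camera at the preset correlation, while fry did not pass (adjusted p = 0.0896 and 0.108). Of 29 neurotrophin receptor and neuropeptide genes, 8 rose, 2 fell and 19 did not pass (11 rose and 3 fell adjusted over the list alone), with a median of 0.23, or 0.14 above the median of all genes. The granin genes SCG2 and CHGB rose 2.06-fold and 1.59-fold, the neuropeptide gene NPY 1.62-fold and the GDNF-family receptor gene GFRA3 2.05-fold, while the neuropeptide genes VIP and NMU fell 1.76-fold and 1.49-fold. On the LSD1+8a shRNA arrays GFRA3 read 8.23 and 7.13 (control mean 6.64) and VIP 6.86 and 7.68 (control mean 8.09). Replicate 1 thus carries much of both differences. Of 37 synaptic genes, 9 rose, 1 fell and 27 did not pass, the same counts as adjusted over the list alone, with a median of 0.19, or 0.11 above that of all genes. SYN1, a synaptic vesicle protein, rose 1.64-fold, SV2A 1.41-fold and SYP, synaptophysin, 1.31-fold, and the adhesion gene NLGN1 fell 1.58-fold. Limma's camera gave adjusted p-values of 0.0260 and 0.00691 for the 2 lists. Neither passed with an estimated correlation (adjusted p = 0.490 for both), and the synaptic list had an adjusted p of 0.0502 without LSD1+8a replicate 1. After cyclic loess 7 neuropeptide genes were called higher and 1 lower, and GFRA3, VIP and NMU were no longer called (adjusted p = 0.0955, 0.0917 and 0.0536). Their log2 differences there were 1.03, -0.77 and -0.74.

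Growth cone, guidance and channel genes moved in part. Of 27 neuronal cytoskeleton genes, 6 rose and 0 fell, also adjusted over the list alone, with a median of 0.11. These were GAP43, a growth cone protein (1.93-fold), DCX, doublecortin (1.83-fold), MAP1A (1.39-fold), the neurofilament gene NEFM (1.37-fold), and the kinesins KIF5A (1.36-fold) and KIF1A (1.34-fold). The list did not pass as deposited (camera adjusted p = 0.175) and passed after cyclic loess (median 0.19, adjusted p = 8.03e-05), after quantile normalization (median 0.22, adjusted p = 6.17e-04) and without control replicate 2 (adjusted p = 0.0283). Its median turned to -0.01 when array medians were centred. Of 50 axon guidance and adhesion genes, 10 rose and 6 fell (10 and 8 adjusted over the list alone), with a camera adjusted p of 0.689. Beside UNC5D, SEMA3C and PCDH17, the semaphorin SEMA3A fell 2.12-fold, and the receptors PLXNA2 and ROBO2 rose by 0.84 and 0.81 on the log2 scale. ROBO2 started from 4.46, within the background medians, and had no call after cyclic loess (adjusted p = 0.0635). Of 46 ion channel and receptor genes, 8 rose and 2 fell (10 and 2 adjusted over the list alone), among them the nicotinic receptor subunit CHRNB4 (0.46 higher on the log2 scale) and the potassium channel KCNT2 (-0.59). That list had a camera adjusted p of 0.0874, and of 0.0318 without LSD1+8a replicate 2. After cyclic loess 3 of its members were called higher and 1 lower, against 10 and 0 of the cytoskeleton list.

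Genes downstream of the 2 differentiating agents went both ways. Of 28 retinoic acid response genes, 8 rose and 4 fell (10 and 5 adjusted over the list alone; camera adjusted p = 0.175). STRA6, the retinol transporter, rose 1.80-fold and CYP26B1, which degrades retinoic acid, 1.39-fold, and ALDH1A3, a retinoic acid synthase, fell 1.59-fold. Of 40 immediate early and ERK response genes, 11 rose and 5 fell (15 and 7 adjusted over the list alone; camera adjusted p = 0.579). The ERK phosphatases DUSP5 and DUSP4 rose 1.56-fold and 1.41-fold, while DUSP6, SPRY2 and SPRED1, feedback inhibitors of the same pathway, fell 1.44-fold, 1.46-fold and 1.35-fold. Of 28 adrenergic neuroblast genes, 5 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.913). GATA3 rose 1.38-fold and CYB561 1.70-fold, and the transcription factor genes ISL1 and SOX11 fell 1.38-fold and 1.47-fold. Of 27 neuronal splicing regulators, 4 rose and 3 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.999), with CELF4 1.52-fold higher and PTBP2, MBNL2 and QKI 1.53-fold, 1.43-fold and 1.41-fold lower. After cyclic loess, 4 retinoic acid response genes were called higher and 1 lower, 3 and 2 immediate early genes, and 3 and 1 adrenergic genes. Of the genes named here, CYP26B1, DUSP5, SPRY2, SPRED1 and ISL1 were not called after cyclic loess (adjusted p = 0.0512, 0.0545, 0.0561, 0.0585 and 0.0528). Their log2 differences there were 0.48, 0.63, -0.47, -0.44 and -0.31.

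Cholesterol synthesis genes were higher and interferon-stimulated genes lower. Of 20 cholesterol genes, 9 rose, 0 fell and 11 did not pass (14 rose adjusted over the list alone), with a median of 0.57. Beside DHCR7, HMGCS1 rose 2.18-fold, MVD 1.78-fold, SQLE, a rate-limiting enzyme of sterol synthesis, 1.71-fold and LSS 1.59-fold. The spread was large in control cells, with HMGCS1 at 7.30 ± 0.66 and DHCR7 at 8.78 ± 0.55 (SD, n = 2). Limma's camera gave an adjusted p of 3.19e-04, which was 0.710 with an estimated correlation and 0.0670 without control replicate 1 (median 0.36). After cyclic loess, HMGCS1 (adjusted p = 0.0519) and SQLE (0.0518) were not called, with log2 differences there of 1.18 and 0.89. The list had a median of 0.61 there and passed camera (adjusted p = 2.35e-06). Of 37 interferon-stimulated genes, 16 fell, 1 rose and 20 did not pass (18 and 4 adjusted over the list alone), with a median of -0.35. IFI6 fell from 11.27 ± 0.42 to 10.07 ± 0.21 (SD, n = 2), which is 2.29-fold, and RIGI, an RNA sensor, fell 2.30-fold. DDX60 had means of 4.89 and 3.71 and IFIT1 of 3.98 and 2.98 in control and LSD1+8a shRNA cells. Against the array medians of background features of GC counts 13 to 18 (4.43 to 4.72), IFIT1 was lower in both groups and DDX60 with the LSD1+8a shRNA, so no size is given. The camera adjusted p was 3.09e-05, and 0.616 with an estimated correlation. It was 0.174 when only genes above the median level were kept, and the median was -0.59 without control replicate 1.

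Among chromatin and stress lists, that of H3K9 methylation passed the test at the preset correlation, and those of LSD1, p53, stress and hypoxia did not. Of 21 genes of the LSD1 and CoREST complex, 3 fell and 1 rose (2 and 0 adjusted over the list alone), with a median of -0.08 and a camera adjusted p of 0.05003, just over the threshold. Without control replicate 1 it was 0.0382, and 0.0348 with array medians centred. Beside KDM1A, REST, the repressor of neuronal genes, fell 1.41-fold and the deacetylase gene HDAC2 1.26-fold, and GSE1 rose 1.25-fold. Of 25 genes that write, erase or read H3K9 methylation, 5 fell and 0 rose, also adjusted over the list alone, with a median of -0.15, or -0.23 relative to all genes. SUV39H2, an H3K9 methyltransferase, fell 1.53-fold, the reader gene CBX3 1.42-fold, and JMJD1C and KDM7A of the demethylase family 1.38-fold and 1.27-fold. The camera adjusted p was 0.00352, and it was 0.490 with an estimated correlation, 0.0526 without LSD1+8a replicate 2 and 0.123 for genes above the median level. HDAC2 and CBX3 were not called after cyclic loess (adjusted p = 0.0632 and 0.0582), with log2 differences there of -0.34 and -0.40. Of 24 p53 targets, 4 fell and 0 rose (camera adjusted p = 0.0786, and 0.0166 without control replicate 1), among them PMAIP1 (1.36-fold) and MDM2 (1.31-fold). Of 32 unfolded protein and stress genes, 1 rose (SLC7A5, 1.86-fold) and 1 fell (PSAT1, 1.23-fold), with a median of 0.01 although camera placed the list lower than other genes (adjusted p = 0.391), and its median was -0.11 with array medians centred. Of 32 hypoxia and glycolysis genes, 1 rose (ALDOC, 1.45-fold) and 3 fell, among them PGK1 (1.34-fold), with a camera adjusted p of 0.328, and of 0.0163 without control replicate 1. Adjusted over the list alone, 4 p53 targets fell, 1 stress gene rose and no hypoxia gene was called. After cyclic loess 1 member was called higher and 1 lower in the LSD1 list and in the p53 list, 1 and 0 in the stress list, and none in the hypoxia list. MDM2, PSAT1, ALDOC and PGK1 were not called there (adjusted p = 0.0723, 0.141, 0.0518 and 0.102).

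Markers of other cell types were mostly dim. Of 18 immune and endothelial markers, 7 rose and 0 fell (11 rose adjusted over the list alone), with a median of 0.27, or 0.19 above that of all genes, and a camera adjusted p of 9.41e-04 (0.616 with an estimated correlation). TYROBP rose 1.38-fold, and PECAM1 was dim in both groups, at 3.98 in control cells and 4.32 with the LSD1+8a shRNA. After cyclic loess TYROBP was called and PECAM1 was not (adjusted p = 0.0386 and 0.123), and 1 of the 18 was called in all. The list still passed camera there (adjusted p = 0.00783, median 0.178). Olfactory receptor genes, which these cells should not express, had a median of 0.17 over 358 genes, with 54 called higher and 0 lower. The background features of GC counts 13 to 18 had a median difference of 0.245, and those of counts 3 to 10 differed by -0.0771 to -0.0121. Of 16 Schwann and glial markers, 4 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0882), with SOX10 1.27-fold higher, and after cyclic loess 0 members were called higher and 1 lower. Of 39 mesenchymal markers, 6 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.202). VIM, vimentin, fell 1.65-fold from 9.36 ± 0.12 to 8.64 ± 0.09 (SD, n = 2), LUM fell 1.49-fold and NOTCH2 1.29-fold. The list had a median of 0.16, which was 0.10 without control replicate 2. For the 15 members above the median gene's level it was 0.088, with 3 falling and 1 rising. After cyclic loess, 1 of the 39 was called higher and 3 lower, with a median of 0.0675.

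**Figure D3:**
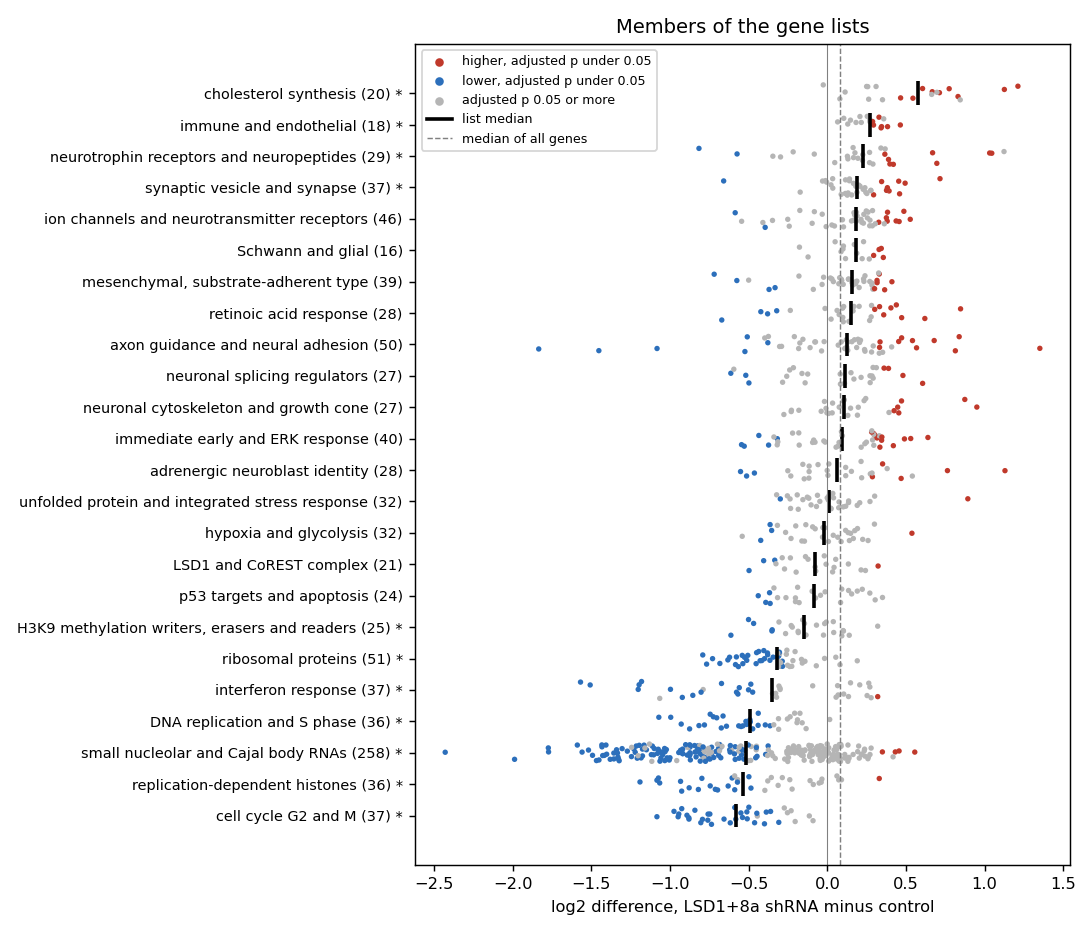
Each point is a measured member of a gene list, with its log2 difference between LSD1+8a shRNA and control on the x axis and the number of members in brackets. Black bars are list medians, the dashed line is the median of all genes (0.08), and stars mark the 11 lists past a camera adjusted p of 0.05, from cholesterol synthesis (0.57) to G2 and mitosis (-0.58).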

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

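The tests of GC background, of other short RNAs, of the brighter mesenchymal markers and of the zinc finger family were chosen after the results had been seen, cyclic loess was chosen after seeing the data, and the other tests in this part were chosen before. ACTA2 and FN1 were named after their values were seen. Bootstrap intervals in this part resampled the genes of a set, and the exact interval ranks them. Neither holds the spread between arrays, and both treat genes of the same arrays as independent.

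Background features, which measure no gene, differed between the groups by GC count: those of counts 13 to 18 were higher on both LSD1+8a shRNA arrays than on both control arrays, by a median of 0.245 on the log2 scale (0.087 to 0.267), as were 10 of all 23 counts, while counts 3 to 10 differed by -0.0771 to -0.0121 and count 25 by -0.0621. Genes with a mean signal of 3 to 6 were higher by a median of 0.175. Olfactory receptor genes (358) lay above the 20 genes nearest to each in level by a median of 0.064 (95% bootstrap interval 0.044 to 0.083). Genes without expected expression were thus not less shifted than others of their level. Those others may be unexpressed too, so this does not separate background from an effect on expressed dim genes. A background difference between the arrays that depends on GC content may therefore account for the rise of dim genes. Dim immune and endothelial markers are among these, and that list still passed camera after cyclic loess (adjusted p = 0.00783, median 0.178). A shift by level alone thus does not cover that list. Cyclic loess works by level and not by GC content, so this result does not weigh against a background difference by GC content. TYROBP, at a mean of 6.96 above the range of dim genes used here, was still called. Background features of GC counts 20 and 21 read 6.63 to 7.34, and both LSD1+8a shRNA arrays lay above both control arrays there. The level of TYROBP thus does not set it apart from background. An effect of the shRNA on dim genes stays open and was not tested, since array background and group go together in these 4 arrays.

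Small nucleolar and Cajal body RNAs were lower. A shift that depends only on signal level is argued against, since their median after cyclic loess was -0.527 (interval -0.639 to -0.365). Other short RNAs above the median level were lower too, by a median of -0.885 (interval -0.950 to -0.797, 72 genes, many of them copies that share probes), so a lower recovery of short RNAs in the LSD1+8a shRNA samples is a candidate explanation. Lower host transcripts cannot be told apart from this. Only host genes named SNHG or GAS5 were looked for, of which 4 were measured (median -0.210, interval -0.424 to -0.010). Host genes with other names were not examined. MicroRNA genes, not part of these tests, had 189 of 1040 called higher and 26 lower. They were not restricted by level, and dim genes were higher in these arrays. These counts therefore do not decide how short RNAs were recovered. A change in the cells' small RNAs after the LSD1+8a shRNA stays open and was not tested.

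Cell cycle and replication genes were lower. A shift by signal level is argued against by their median of -0.527 after cyclic loess (interval -0.620 to -0.455), and a p53 response by the median of the p53 targets (-0.086, interval -0.203 to 0.092). Fewer cells of a mesenchymal type are argued against as the whole cause, since the markers had a median of 0.156 (interval 0.078 to 0.230; 0.0675 after cyclic loess), and the 15 above the median gene's level one of 0.088 (exact interval -0.181 to 0.283), against -0.259 for the bound set from the cell cycle median. VIM (-0.72), NOTCH2 (-0.37) and TWIST1 (-0.33) fell, ACTA2 (0.33) rose and FN1 was at -0.50 without passing the test, and without LSD1+8a replicate 2 the lower end for the brighter markers was -0.277 against -0.275. A bias by GC content cannot be told apart from an effect of the shRNA, since no sequence was used: the ZNF zinc finger genes, outside the cell cycle, were lower as well, by a median of -0.171 (interval -0.195 to -0.134). Slower division after the LSD1+8a shRNA may contribute and stays a hypothesis, as do off-target effects of the shRNA, which no second shRNA in these 4 arrays checks.

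Transcript clusters without a gene name, which the report does not use, also differed. Over all transcript clusters, 94 unnamed clusters passed a limma adjusted p of 0.05 as higher and 367 as lower, out of 42204. TC0X001292.hg.1 differed by -2.29 on the log2 scale, the most among lower ones.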

How the results depend on the processing

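Cyclic loess and the restriction to protein-coding genes were chosen after seeing the data. Outside the settings that leave out an array, none of the 148 genes that the naming rule takes beside KDM1A changed sign. Of gene and setting pairs, 138 lost their call, 866 stayed as they were and 1 gained a call. The losses were 46 under cyclic loess, 42 under centring, 35 under quantile normalization and 15 under trended moderation. With an array left out, none of these genes changed sign either. The groups did not overlap for any of them, so leaving out an array could not have changed a sign. Most pairs of gene and left-out array lost their call. The number of called genes (5245, with 2721 higher and 2524 lower) was 3315 after quantile normalization (1433 higher), 2611 after cyclic loess (702 higher), 881 over all transcript clusters (150 higher, 731 lower), 9576 at an adjusted p of 0.1 (5704 higher, 3872 lower) and 805 with a 1.5-fold limit (135 higher, 670 lower). The higher calls alone moved to 384 with array medians centred, 1323 without dim genes and 1365 with cyclic loess among protein-coding genes. Leaving out 1 array gave 0 to 2834 calls, 0 to 860 higher and 0 to 1974 lower. Fewer arrays and another number of features tested may account for part of this, and the causes were not tested. The nominal 1.5-fold set (858, with 143 higher and 715 lower) moved to 1401 with medians centred (67 higher, 1334 lower), to 545 among protein-coding genes (433 lower) and to 91 higher without dim genes. With 1 array left out it held 669 to 1335 genes, 130 to 332 higher and 539 to 1016 lower.

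The replicate numbers did not pair the arrays: over genes, the deviations of same-numbered arrays had a correlation of 0.02. With the replicate number as a block, 7954 genes were called (4425 higher), and the number of lists stayed at 11. KDM1A differed by -0.28 after quantile normalization and -0.29 after cyclic loess, both no longer past the threshold, and by -0.48 to -0.33 with 1 array left out.

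The number of lists past the threshold (11) was 9 to 13 under the other settings of camera, and 0 with an estimated correlation and 0 with fry, where the medians stay as they are: 0.19 for synaptic, 0.23 for neuropeptide, 0.27 for immune, -0.58 for mitosis, -0.49 for S phase, -0.35 for interferon, 0.57 for cholesterol, -0.15 for H3K9, -0.32 for ribosomal, -0.51 for small nucleolar and -0.53 for histone genes. Without dim genes the interferon list (median -0.58) and the H3K9 list (-0.17) no longer passed. The cytoskeleton list came to pass after quantile normalization (0.22), without dim genes (0.10) and after cyclic loess (0.19). The LSD1 list passed with medians centred (-0.20). Medians of lists that did not pass changed sign under centring for cytoskeleton (-0.0141), immediate early (-0.0295), adrenergic (-0.0589), stress (-0.11) and splicing genes (-0.0130), for axon guidance without dim genes (-0.0205) and for hypoxia after quantile normalization (0.0085). With 1 array left out, medians ran from 0.0938 to 0.1217 for cytoskeleton, 0.1781 to 0.1999 for synaptic, 0.1620 to 0.2144 for ion channel, -0.2062 to -0.0156 for p53, -0.0354 to 0.0432 for stress, 0.3581 to 0.7358 for cholesterol, -0.0793 to 0.0696 for hypoxia, -0.1527 to -0.0521 for LSD1 complex, -0.1737 to -0.1043 for H3K9, -0.5856 to -0.2842 for small nucleolar, -0.5887 to -0.2558 for interferon, 0.1025 to 0.2007 for mesenchymal, 0.0672 to 0.2774 for immediate early and 0.0157 to 0.1566 for adrenergic genes. Without dim genes the immune list had too few members for a test. With 1 array left out, the lone array of its group is assumed to vary like the other pair.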

Other observations

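The gene families, the copies and the count of splits were examined after the results of the report had been seen. Grouping protein-coding genes by the letters at the start of their symbols gave 228 families of at least 10 measured members, of which 82 passed limma's camera at the preset correlation and 55 did so both as deposited and after cyclic loess. Centrosome genes (CEP) were lower, with 16 of 36 falling, 1 rising and a median of -0.33 (adjusted p = 1.39e-07). Nucleoporin genes (NUP) had 13 of 23 falling and none rising, with a median of -0.36, and the splicing factor genes SRSF had 6 of 10 falling and none rising, with a median of -0.34. Mitochondrial ribosomal proteins of the large subunit (MRPL) had 16 of 48 falling and none rising, and intraflagellar transport genes (IFT) 7 of 18. Zinc finger genes (ZNF) had 115 of 479 falling and 12 rising. None of the families passed with an estimated correlation, a test with little power on 4 arrays. The adjusted p there was 0.697 for each of those named here.

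Other families had more members higher or none called. Keratin-associated protein genes (KRTAP) had 24 of 86 rising and none falling (median 0.26, and 0.14 after cyclic loess), and immunoglobulin V segments 59 of 155 rising and none falling (median 0.29, and 0.16 after cyclic loess). The V segments were not tested as a set. Their median level was 5.25, and all genes at levels of 5 to 6 had a median difference of 0.21. A background difference was not separated from a change in these genes. Taste receptor genes (TAS) had 3 of 26 rising and 2 falling (median -0.04, and -0.11 after cyclic loess), and none of 13 interferon alpha genes (IFNA) was called (median 0.10).

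Within the small nucleolar RNAs, the imprinted SNORD116 copies were lower, with a median of -1.06 and 18 of 19 called, while the 31 SNORD115 copies of the neighbouring cluster had a median of -0.04 and none called. The SNORD115 copies had a median level of 2.04, at the bottom of the scale, where a change would hardly be measurable. The SNORD116 copies are similar in sequence and are not independent of each other.

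With 4 arrays there are 3 ways to split them into 2 and 2, too few for a share under 0.05. The real split called 5245 genes and 1 of the 3 splits reached that number, the real one. The highest of the other splits called 0, with 86 genes at an unadjusted p under 0.05. Each other split puts 1 array of either group on each side, so the group difference adds to its spread and leaves few calls. The low count there is therefore no test of the real split.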
